A study of Mus musculus with 4 samples.

How the data were processed

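The series holds 4 RNA-seq libraries of B16 cells, a mouse melanoma cell line: 2 control libraries and 2 libraries of cells after 4 h with EM-plasma, named in the labels as plasma treated with exosome-mimetic nanovesicles. The sources used here do not say what the plasma was, whether a gas or a blood fraction. They also do not say whether the controls received vehicle, nanovesicles or plasma alone, or when they were collected. Groups and replicate numbers were taken from the sample titles. The libraries are not stated to come from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

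Per the labels' protocols, poly(A) RNA was isolated and libraries were made with a stranded Illumina kit, and the RNA integrity number was above the stated minimum in every sample. Per the submitters' processing notes, the build was GRCm38 and the tools were CASAVA, TopHat2 2.1.1, HTSeq and edgeR, with no role or order given. The annotation release and the strand setting of the counting are not given in the sources used here. The table of counts deposited by the authors holds whole-number reads per Ensembl gene, 1 column per library, with replicates not pooled. The authors also deposited 1 table per sample of a scaled signal. In each of these tables the signal of every gene equalled its count times 1 constant per library. That constant equalled edgeR's TMM-scaled CPM (counts scaled to a fixed library total) to the decimals deposited. The tests used the counts, and the signal tables served only to check the columns.

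The count table had 53465 gene rows. Symbols were found for 53360 of them (99.8%), and 105 rows with no symbol held 0.0060% to 0.0064% of the counts of a library. Coordinates, biotypes, transcript length and GC content came from GENCODE mouse release 21 (Ensembl 96) on GRCm38. Total counts were 49367932 and 47664388 in control 1 and 2, and 46295133 and 46557637 in EM-plasma 1 and 2. Overlapping genes, antisense genes and near-identical copies can share reads, and intervals cover counting error and the spread between these samples only.

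Genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 13664. Libraries were scaled by TMM. The test was edgeR's quasi-likelihood F test with its default settings, which in this version take the legacy dispersion, on group alone with no block. It was two-sided with Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p below 0.05 were called changed. Standard errors are the absolute log2 fold change divided by the square root of F, and intervals are 95% intervals on the fit's total degrees of freedom. CPM values are given as mean ± SD (n = 2 per group) and are counts per library total of the tested genes times its TMM factor. The prior degrees of freedom were 25.5, the biological coefficient of variation was 4.0%, and the median standard error of a log2 fold change was 0.070.

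Before the data were examined, 32 gene lists were fixed, covering Golgi, ferroptosis, stress, lipid, growth, pigment and inflammatory genes and markers of other cell types. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 30 lists that had at least 5 tested members. Each list was also tested with an estimated correlation and with fry, and its members were adjusted over the list alone. With an estimated correlation camera takes its degrees of freedom from the residuals, which are few with 4 libraries. A call lost there can come from that as well as from correlation between members. The genes named in the text were chosen by a rule fixed at the same time. The rule took the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 CPM. Predicted genes, Riken clones, numbered pseudogenes and rows with no symbol were passed over. It added up to 2 called members per list by smallest adjusted p, the most abundant member of a list with none, and 17 genes of ferroptosis, Golgi stress, cell stress and pigmentation named in advance. This gave 70 tested genes. Other members that the text names were chosen after their values were seen.

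Counts were simulated from the means and library sizes of these libraries with 200 changed genes, and 13490 genes entered that fit. The test called in the right direction 38 of 79 genes (48.1%) changed 1.2-fold, 54 of 76 (71.1%) changed 1.5-fold and 32 of 40 (80%) changed 2-fold. It called 3 of 13295 unchanged genes. The simulated counts held no trend shared by the genes of a library, so this share does not cover false calls from such a trend. Of 20 simulated lists shifted by 0.2 on the log2 scale camera called 20, and of 20 unchanged lists it called 0. The genes were drawn independently, so these lists held no correlation between members and do not test the preset value. In the real data the estimated correlation reached 0.47, in the ribosomal protein list.

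The alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, library totals), other filters, DESeq2's Wald test, limma voom and edgeR's exact test. They also included the replicate number as a block, an adjusted p below 0.01, a test against a fold of 1.2, and each library left out in turn. In these last fits the group with 1 library was assumed to vary like the other group. Removal of a per-library trend in GC content or transcript length, and edgeR's newer dispersion, were added after seeing the data. Splits of the samples other than the real one were not counted, because the groups hold 2 libraries each.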

Results

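Poly(A) RNA of B16 mouse melanoma cells was sequenced in 4 libraries, 2 of control cells and 2 of cells collected after 4 h with EM-plasma. The total count per library ran from 46295133 to 49367932, and between 18954 and 19493 genes had at least 1 read. The 10 most abundant genes took between 2.64% and 2.69% of the counts of a library. The comparison asked which transcripts differ between treated and control cells, and the series title places it in work on Golgi stress and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. Gene positions are on GRCm38, with the Ensembl identifier of the count table. Gene values are CPM as mean ± SD (n = 2 per group) and log2 fold changes of EM-plasma against control. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists are from camera.

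In EM-plasma-treated cells 23 of 35 tested targets of the amino acid stress factor ATF4 and 13 of 30 antioxidant targets of NRF2 were higher than in controls, while 15 of 27 sterol genes and 13 of 33 interferon-response genes were lower. Camera called these 4 lists at its preset correlation but not with an estimated one (adjusted p = 0.299, 0.224, 0.224 and 0.224 with an estimated correlation). The estimate was 0.11 for the ATF4 list. It was -0.017, -0.028 and -0.010 for the NRF2, sterol and interferon lists, below the preset 0.01. The calls in these last lists were therefore not lost through a larger estimate. With few residual degrees of freedom the estimates are themselves uncertain, and correlation between members is not excluded. Slc7a11, the cystine importer subunit that feeds glutathione synthesis, rose 1.79-fold, from 60.5 ± 2.16 to 108 ± 0.0586 CPM. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose 1.72-fold, from 103 ± 6.92 to 177 ± 0.366 CPM. Of 27 tested members of a Golgi stress list 0 rose and 2 fell, with a median log2 fold change of 0.023. Of 13664 tested genes 849 changed (6.21%), 456 higher and 393 lower, and 83 of them changed at least 2-fold, 67 higher and 16 lower. Most changes were small: 348 of the called genes changed by less than 1.2-fold and 342 by 1.2-fold to 1.5-fold, with a median absolute log2 fold change of 0.30. At an unadjusted p below 0.05 there were 2671 genes. Fits that left out 1 library called fewer genes, fewest without control 2, but each also estimated the variance differently. The coefficient of variation was 2.44% without either control and 5.01% without either EM-plasma library, against 4.0% with all libraries. Total degrees of freedom were 5.71 without control 1 and 5.27 without control 2, against 27.5. The drop therefore does not measure the weight of the left-out library alone. Of all tested genes 49.1% had both treated libraries on one side of both controls, against 33.3% by chance.

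**Figure D1:**
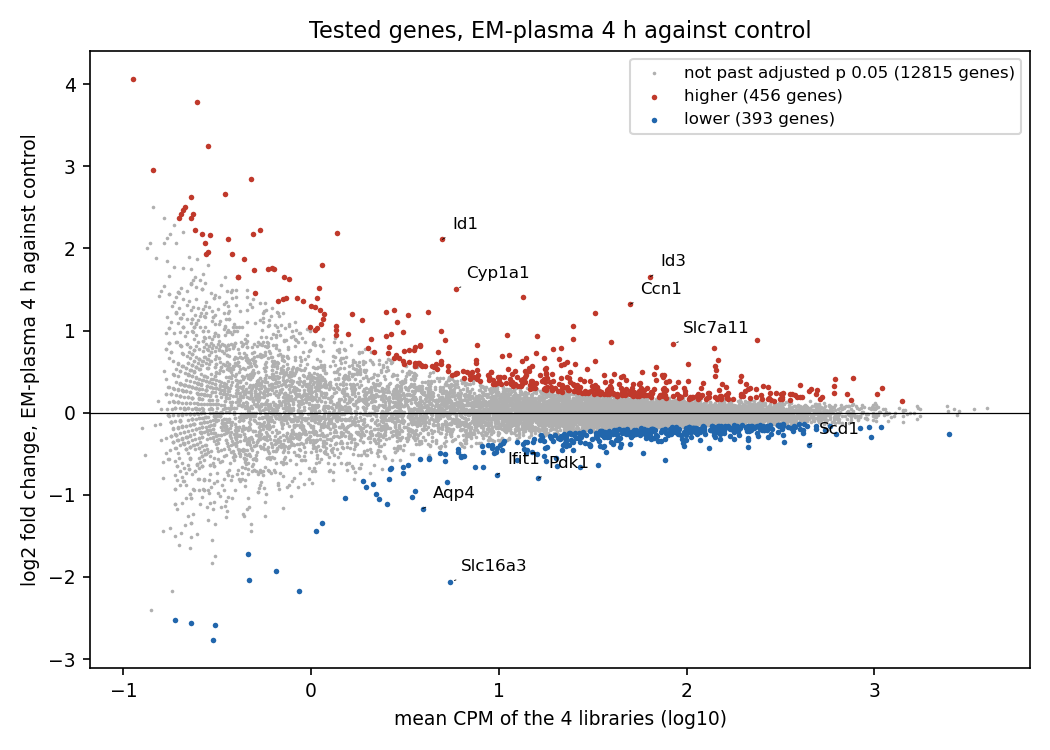
Log2 fold change of EM-plasma 4 h against control (vertical axis) against the mean CPM of the 4 libraries on a log10 scale (horizontal axis), 1 point per tested gene. Red points are the 456 genes called higher, blue points the 393 called lower and grey points those not past an adjusted p of 0.05; Id1 lies at 2.11 and Slc16a3 at -2.06.

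The largest rises that met the naming rule were in Id1 and Id3, genes of helix-loop-helix proteins that inhibit differentiation factors. Id1 (chromosome 2, 152736251 to 152737410, ENSMUSG00000042745) rose 4.31-fold, from 1.88 ± 0.477 to 8.13 ± 0.0545 CPM (log2 fold change 2.11, SE 0.17, adjusted p = 6.79e-10). Id3 (chromosome 4, 136143497 to 136145755, ENSMUSG00000007872) rose 3.15-fold, from 30.8 ± 5.66 to 97.2 ± 0.50 CPM (log2 fold change 1.65, SE 0.077, adjusted p = 1.23e-14). Cyp1a1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, rose 2.84-fold, and Ccn1, a secreted matricellular protein gene, rose 2.5-fold. Etv4, an ETS-family transcription factor gene, rose 2.34-fold and Lims2, a focal adhesion gene, 2.32-fold. The largest falls that met the naming rule were led by Slc16a3, the lactate exporter MCT4 (chromosome 11, 120948480 to 120960868, ENSMUSG00000025161). Slc16a3 was 4.17-fold lower, at 2.14 ± 0.0175 against 8.9 ± 2.44 CPM (log2 fold change -2.06, SE 0.17, adjusted p = 2.53e-09). Aqp4, a water channel gene, was 2.25-fold lower, and Nrep, a neuronal regeneration gene, 1.8-fold lower. Pdk1, the kinase that restrains pyruvate dehydrogenase, was 1.74-fold lower. The interferon-induced genes Ifit1 and Ifit3 were 1.69-fold and 1.58-fold lower. Id1, Id3, Cyp1a1, Ccn1, Lims2 and Slc16a3 passed in all 4 fits that left out a library. The calls of Etv4, Aqp4, Nrep, Pdk1, Ifit1 and Ifit3 ended without control 2, with adjusted p = 0.0804, 0.277, 0.0929, 0.0733, 0.086 and 0.128, and that of Aqp4 also without control 1 (adjusted p = 0.0802).

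Targets of ATF4, the transcription factor that raises amino acid transport and synthesis when translation initiation is restrained, rose in 23 of 35 tested members, and 1 fell (28 and 1 adjusted over the list alone). The list's median log2 fold change was 0.23 (camera adjusted p = 1.82e-14; adjusted p = 0.299 with an estimated correlation). Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254, ENSMUSG00000029752), rose 1.3-fold, from 167 ± 7.37 to 218 ± 3.88 CPM (adjusted p = 3.73e-06). Chac1, a glutathione-degrading enzyme, rose 1.38-fold (adjusted p = 0.000493) and Ddit3, the stress transcription factor CHOP, 1.26-fold (adjusted p = 0.00448). Atf4 itself rose 1.13-fold, from 238 ± 0.67 to 268 ± 0.479 CPM (adjusted p = 0.016). Trib3, Slc6a9, Nupr1, Atf3, Pck2 and the tRNA synthetase genes Aars, Gars, Nars and Sars were also among the members that rose. The member that fell was Ddit4, an inhibitor of mTORC1 signalling (log2 fold change -0.31). Members called higher numbered 19 without control 1, 6 without control 2, 13 without EM-plasma 1 and 12 without EM-plasma 2, and the list was called in each of these fits. The calls of Chac1, Ddit3 and Atf4 ended without control 2 (adjusted p = 0.13, 0.151 and 0.0997), and those of Ddit3 and Atf4 also without EM-plasma 1 (0.157 and 0.44) or EM-plasma 2 (0.0574 and 0.397).

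Targets of NRF2, the transcription factor of the antioxidant response, rose in 13 of 30 tested members and fell in 0 (18 and 1 adjusted over the list alone). The median log2 fold change was 0.15 (camera adjusted p = 5.71e-08; adjusted p = 0.224 with an estimated correlation). Hmox1 (chromosome 8, 75093621 to 75100589, ENSMUSG00000005413) had a log2 fold change of 0.78 (SE 0.052, adjusted p = 1.82e-11). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose 1.51-fold, from 81.2 ± 1.28 to 123 ± 1.73 CPM (adjusted p = 5.51e-09). Srxn1, Osgin1, Gclc, Txnrd1, G6pdx, Pgd, Taldo1, Slc48a1 and Sqstm1 rose as well, with log2 fold changes from 0.17 to 0.65. Slc7a11 and Trib3 were called members of both this list and the ATF4 list. Members called higher numbered 13 without control 1, 7 without control 2, 8 without EM-plasma 1 and 6 without EM-plasma 2, and Slc7a11, Hmox1 and Gclm passed in each.

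Genes of ferroptosis defence moved both ways: 6 of 23 tested members rose and 3 fell (8 and 4 adjusted over the list alone). The median log2 fold change was 0.12 (camera adjusted p = 0.0117; adjusted p = 0.543 with an estimated correlation), and without control 1 the list was not called (adjusted p = 0.0724). Slc7a11 (chromosome 3, 49892526 to 50443614, ENSMUSG00000027737, log2 fold change 0.84, SE 0.055, adjusted p = 1.61e-11), its partner Slc3a2, Gclm, Gclc, Txnrd1 and the iron exporter Slc40a1 rose. Acsl3, which activates monounsaturated fatty acids, and the desaturases Scd1 and Scd2 fell, and these belong to lipid synthesis as well. Of those that rose, Slc7a11, Gclm, Gclc and Txnrd1 were also called members of the NRF2 list, and Slc7a11 and Slc3a2 of the ATF4 list. Gpx4, the peroxidase that removes lipid hydroperoxides, was at 183 ± 2.44 CPM in controls and 188 ± 1.48 CPM in treated cells, with a log2 fold change of 0.037 (95% interval -0.058 to 0.13, adjusted p = 0.726). Of 26 tested genes of ferroptosis promotion and its markers, 3 rose (Hmox1, Chac1 and Keap1) and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.741). That list's median was -0.031, with camera's direction lower, while its mean lay above 0 and fry's direction was higher (adjusted p = 0.886). The 3 that fell act in making polyunsaturated phospholipids: Acsl4 (-0.25 on the log2 scale, adjusted p = 0.0198), Lpcat3 and Fads1. The call of Acsl4 ended whichever library was left out, with adjusted p from 0.0561 to 0.587, and so did those of Lpcat3 and Fads1, as 0 members of this list were called lower in each of these 4 fits. Members of it called higher numbered 2, 1, 2 and 2 without control 1, control 2, EM-plasma 1 and EM-plasma 2, and those of the defence list 5, 4, 4 and 3, with 3, 2, 3 and 3 called lower. Ptgs2, a transcript often used as a ferroptosis marker, had 1 read in control 1 and 0 in the other libraries and was not tested.

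Iron handling genes showed 2 of 19 tested members higher, Hmox1 and Slc40a1 (adjusted p = 0.0151), and 0 lower (3 and 0 adjusted over the list alone; 1 called by DESeq2; camera adjusted p = 0.18), and fry called the list higher (adjusted p = 0.0257). The call of Slc40a1 ended whichever library was left out (adjusted p from 0.0711 to 0.207). Tfrc, the transferrin receptor, was at 493 ± 24.8 CPM in controls and 459 ± 14.5 CPM in treated cells (adjusted p = 0.184). Fth1, the ferritin heavy chain, was at 971 ± 18.8 and 1052 ± 21.5 CPM (adjusted p = 0.0741). Neither passed the test.

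The Golgi stress list holds genes of the TFE3 and CREB3 branches, which act when Golgi capacity falls short. Of its 27 tested members 0 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.544; 4 members had an unadjusted p below 0.05, and DESeq2, voom and the exact test each called 2). The list's median log2 fold change was 0.023, with 17 of 27 members above 0. Both camera and fry gave it the direction higher (fry adjusted p = 0.378). Members called higher numbered 2 with the replicate block and 1 after a GC or a length trend was removed, with 2 lower in each. The 2 that fell in the reported fit were Ets1, a transcription factor gene (-0.21 on the log2 scale, adjusted p = 0.00141), and Sdc4, a syndecan core protein gene (-0.20, adjusted p = 0.0276). Arf4, a small GTPase induced through CREB3, was at 261 ± 9.22 CPM in controls and 261 ± 5.28 CPM in treated cells, with a 95% interval of the log2 fold change from -0.10 to 0.09 (adjusted p = 0.982). The interval was -0.048 to 0.22 for Creb3, -0.046 to 0.18 for Tfe3 and -0.015 to 0.19 for Golga2, the gene of the cis-Golgi matrix protein GM130 (adjusted p = 0.522, 0.548 and 0.355). Of 42 tested genes of Golgi structure and vesicle coat 0 rose and 1 fell, Cog5 (-0.23 on the log2 scale, adjusted p = 0.0166), again with the same counts adjusted over the list alone (camera adjusted p = 0.961). In this list 1 gene was called higher and 2 lower after a GC trend was removed. The replicate block and the exact test each called 0 higher and 2 lower. The calls of Ets1 and Cog5 ended without control 2 (adjusted p = 0.0804 and 0.198), EM-plasma 1 (0.196 and 0.411) or EM-plasma 2 (0.115 and 0.223), and that of Sdc4 whichever library was left out (adjusted p from 0.10 to 0.533).

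In the reported fit the ER chaperone, heat shock and metal response lists held 0 called genes. Of 29 tested ER chaperone genes 0 passed, with 7 at an unadjusted p below 0.05 and 0 called by DESeq2 (camera adjusted p = 0.203). Hspa5, the main ER chaperone BiP, was at 1017 ± 40.8 CPM in controls and 999 ± 33.8 CPM in treated cells (95% interval of the log2 fold change -0.11 to 0.058), and Canx, calnexin, at 1252 ± 66.3 and 1210.5 ± 25.8 CPM. Of 25 heat shock genes 0 passed, with 5 at an unadjusted p below 0.05 and 0 called by DESeq2 and 1 by edgeR's exact test. The most abundant, Hsp90ab1, was at 2439 ± 19.3 and 2475 ± 25 CPM. Of 6 metallothionein and metal response genes 0 passed, with 2 at an unadjusted p below 0.05 and 0 called by DESeq2 and 1 by the exact test, and Mt1 was at 224 ± 13.8 and 216 ± 2.45 CPM. Adjusted over the list alone, 0 ER chaperone, 0 heat shock and 1 metal response gene passed, the last one lower. Camera gave adjusted p = 0.909 for heat shock, with a median of -0.012 and fry's direction higher (adjusted p = 0.886), and 0.744 for metal response. Without control 1, 1 ER chaperone, 4 heat shock and 1 metal response genes were called lower, and in the other 3 fits without a library 0 were called. With the replicate block 1 ER chaperone gene was called higher and 1 lower, 3 heat shock genes lower, and 1 metal response gene higher and 1 lower. After a GC trend was removed 1 ER chaperone gene was called higher, 2 heat shock genes lower, and 1 metal response gene higher and 1 lower. With the newer dispersion 1 metal response gene was called lower.

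Of 27 tested genes of the SREBP2 cholesterol list 15 fell and 0 rose (20 and 0 adjusted over the list alone), and all 27 had a log2 fold change below 0 (26 without control 1, without EM-plasma 1 or after a GC trend was removed), with a median of -0.19 (camera adjusted p = 1.08e-11; adjusted p = 0.224 with an estimated correlation). Nsdhl, a sterol dehydrogenase gene (chromosome X, 72918557 to 72958514, ENSMUSG00000031349), was 1.27-fold lower, at 63.9 ± 1.28 against 81.3 ± 0.375 CPM (adjusted p = 0.000143). Acat2, Pmvk, Dhcr7, Fdft1, Cyp51, Lss, Msmo1, Sc5d and Hmgcs1, also of the synthesis pathway, fell too, as did the regulators Srebf2 and Insig1. The called members Mylip and Abca1 act differently: Mylip degrades the LDL receptor (-0.64 on the log2 scale, adjusted p = 2.99e-06) and Abca1 exports cholesterol (-0.36), and both are targets of the sterol-sensing receptor LXR. Fatty acid synthesis and desaturation genes fell in 9 of 22 tested members and rose in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00368; adjusted p = 0.348 with an estimated correlation). Scd1, stearoyl-CoA desaturase (chromosome 19, 44394455 to 44407879, ENSMUSG00000037071), was 1.31-fold lower, at 388 ± 0.346 against 508 ± 6.52 CPM (adjusted p = 2.25e-07), and Scd2 1.2-fold lower (adjusted p = 1.32e-05). The cholesterol members called lower numbered 12 without control 1, 1 without control 2, 5 without EM-plasma 1 and 3 without EM-plasma 2, those of the fatty acid list 5, 3, 4 and 4 in the same order, and both lists were called in each of these fits. The calls of Nsdhl and Mylip ended without control 2 (adjusted p = 0.0669 and 0.0537), and those of Scd1 and Scd2 held in all 4.

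Interferon-response and antigen presentation genes fell in 13 of 33 tested members and rose in 1 (18 and 1 adjusted over the list alone). The median log2 fold change was -0.35 (camera adjusted p = 1.0e-09; adjusted p = 0.224 with an estimated correlation). Ddx58, the cytosolic RNA sensor RIG-I (chromosome 4, 40203773 to 40239828, ENSMUSG00000040296), was 1.58-fold lower, at 21 ± 0.0527 against 33.2 ± 2.38 CPM (log2 fold change -0.66, SE 0.073, adjusted p = 5.07e-07). Ifit1 had a log2 fold change of -0.75 (adjusted p = 3.8e-05), and Ifih1, Isg15, Irf9, Irf7, Irf1, Rsad2, Bst2, Ifit3 and the class I genes H2-K1 and B2m fell as well. The member that rose was Cxcl10, a chemokine gene, by 1.32-fold, from 41 ± 0.515 to 54.1 ± 0.561 CPM (adjusted p = 6.82e-05). Cxcl10 and Lif, a cytokine gene at 0.288 ± 0.139 CPM in controls and 0.977 ± 0.0748 CPM in treated cells (adjusted p = 0.00986), were the called members of 18 NF-kB inflammatory genes. That list had 2 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.105). Interferon members called lower numbered 7 without control 1, 1 without control 2, 6 without EM-plasma 1 and 8 without EM-plasma 2, and the list was called in each. DESeq2 called 8 interferon members lower and 1 NF-kB gene. Ddx58 held in all 4 fits, while the calls of Ifit1 and Cxcl10 ended without control 2 (adjusted p = 0.086 and 0.0597) and that of Lif whichever library was left out (adjusted p from 0.0549 to 0.22).

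**Figure D2:**
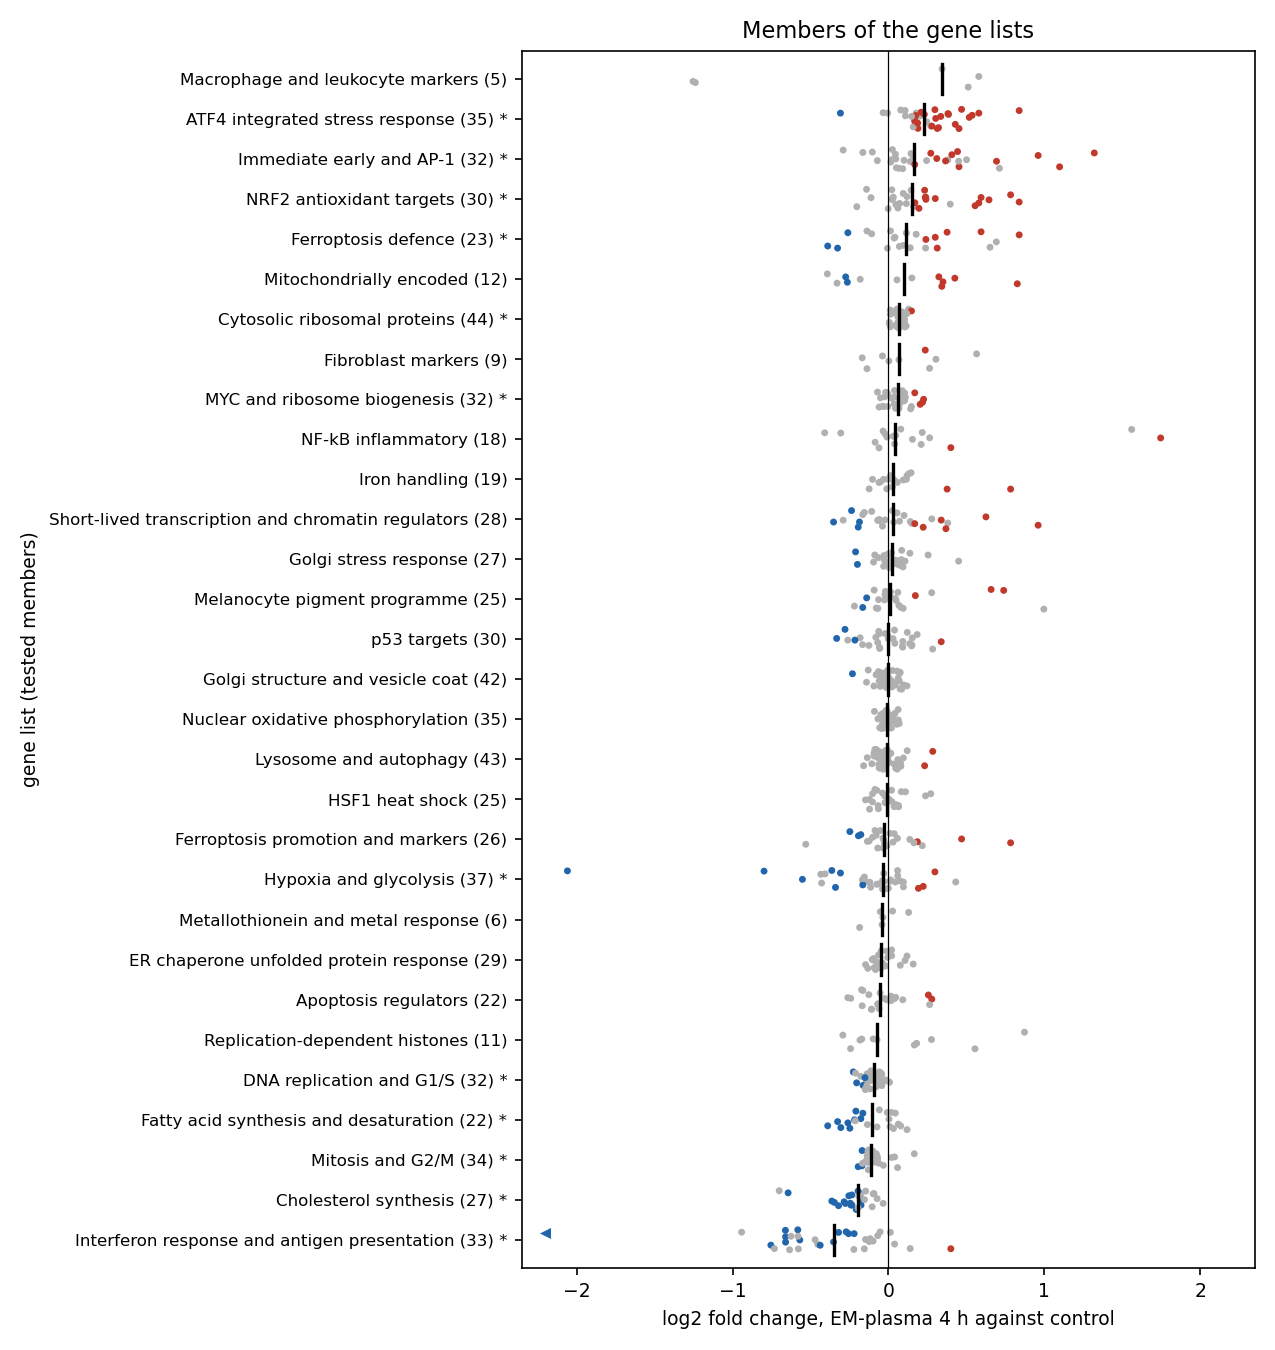
Log2 fold change of EM-plasma 4 h against control (horizontal axis) of each tested member of 30 gene lists (vertical axis, tested members in brackets), with red for members called higher, blue for those called lower, grey for the rest and a black bar at the list median. An asterisk marks the 12 lists called by camera at the preset correlation, none of which was called with an estimated correlation; a triangle marks Irf7, which lies beyond the axis at -2.76.

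Immediate early genes, which respond to growth factor and stress signalling, rose in 11 of 32 tested members and fell in 0 (15 and 2 adjusted over the list alone). The median log2 fold change was 0.16 (camera adjusted p = 4.5e-07; adjusted p = 0.543 with an estimated correlation). Ccn1 (chromosome 3, 145646976 to 145649981, ENSMUSG00000028195) went from 28.6 ± 0.369 to 71.4 ± 5.45 CPM (adjusted p = 3.75e-14), and Dusp4, a MAP kinase phosphatase gene, rose 1.36-fold (adjusted p = 8.17e-07). Fos rose 1.95-fold, from 1.8 ± 0.282 to 3.51 ± 0.292 CPM (adjusted p = 0.00345), and Egr1, Ccn2, Atf3, Zfp36, Dusp6, Fosl2, Junb and Myc were the others that rose. Of 28 short-lived transcription and chromatin regulators 6 rose and 4 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.80). Btg1, an antiproliferative gene, was 1.28-fold lower (adjusted p = 0.00289). Immediate early members called higher numbered 6, 3, 7 and 7 without control 1, control 2, EM-plasma 1 and EM-plasma 2, and 7 by DESeq2. Among the short-lived regulators 0, 0, 1 and 3 were called higher and 1, 0, 1 and 0 lower in these 4 fits, and the exact test called 7 lower. The call of Fos ended without control 1 or control 2 (adjusted p = 0.0789 and 0.11), and that of Btg1 without control 2 or EM-plasma 2 (0.159 and 0.112).

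Hypoxia and glycolysis genes fell in 7 of 37 tested members and rose in 3 (11 and 4 adjusted over the list alone). Slc16a3, Pdk1 (11.8 ± 1.35 against 20.6 ± 0.489 CPM, adjusted p = 8.13e-07), the mitophagy receptors Bnip3 and Bnip3l, Pfkl, Ddit4 and Kdm3a fell, and Hk1, P4ha2 and Ero1l rose. The list's median log2 fold change was -0.038 (camera adjusted p = 0.0444; adjusted p = 0.796 with an estimated correlation), and it was not called without control 1 (adjusted p = 0.393) or EM-plasma 1 (0.129), nor when genes were filtered at CPM above 1 in 2 samples (0.0566). Members called lower numbered 6, 2, 4 and 6 without control 1, control 2, EM-plasma 1 and EM-plasma 2, and members called higher 2, 1, 1 and 1. Of 35 nuclear genes of oxidative phosphorylation 0 passed, with 0 at an unadjusted p below 0.05 and 0 called by DESeq2, 1 after a GC trend was removed, and 0 adjusted over the list alone (camera adjusted p = 0.809), and Atp5b was at 1549 ± 6.29 and 1544 ± 23.9 CPM. Of 12 tested mitochondrially encoded genes 5 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.348). Among them mt-Co1 went from 655 ± 24.9 to 881 ± 5.37 CPM (adjusted p = 2.71e-08) and mt-Nd5 rose 1.27-fold (adjusted p = 3.37e-06). Mitochondrial members called lower numbered 2, 1, 1 and 2 in these 4 fits, and members called higher 5, 4, 5 and 5. Mitochondrial reads can be shared with near-identical nuclear copies and are uncertain for that reason.

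Both cell cycle lists were called lower at the preset correlation. Of 32 DNA replication genes 4 fell and 0 rose (11 and 0 adjusted over the list alone), with a median log2 fold change of -0.095 (camera adjusted p = 3.03e-06; adjusted p = 0.25 with an estimated correlation). Uhrf1, a replication-coupled methylation factor, was 1.15-fold lower (adjusted p = 0.00291) and Pola1, a DNA polymerase subunit, 1.17-fold lower (adjusted p = 0.00971), and Mcm4 and Pcna were the other members called. Of 34 mitosis genes 3 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 1.01e-05; adjusted p = 0.549 with an estimated correlation). They were Mki67 (from 994 ± 48.3 to 885 ± 6.99 CPM, adjusted p = 0.0101), Hmmr (adjusted p = 0.0287) and Ccnb2. Of 32 MYC and ribosome biogenesis genes 4 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.543 with an estimated correlation). They were Odc1, the first enzyme of polyamine synthesis (adjusted p = 0.00134), Fbl, a nucleolar methyltransferase (adjusted p = 0.0144), Nob1 and Myc. Of 44 cytosolic ribosomal protein genes 1 rose, Rps14 (1.11-fold, adjusted p = 0.0425), and 0 passed adjusted over the list alone. With all 4 libraries 44 of 44 had a log2 fold change above 0 (36 without control 1, 39 without EM-plasma 2, and 42 after a GC trend was removed, where 9 were called higher), with a median of 0.068 (camera adjusted p = 5.22e-05; adjusted p = 0.796 with an estimated correlation). Members called without control 1, control 2, EM-plasma 1 and EM-plasma 2 numbered 3, 1, 0 and 0 (lower) in the replication list, 9, 0, 0 and 0 (lower) in the mitosis list and 0, 0, 1 and 0 (higher) in the MYC list. The exact test called 8 replication genes lower, the GC correction 13 and the replicate block 12, and 11 and 15 mitosis genes were called lower under these last 2. The MYC list was not called without control 1 (adjusted p = 0.0628), EM-plasma 1 (0.0716) or EM-plasma 2 (0.240), nor the ribosomal list without EM-plasma 2 (0.234). Without control 2, Uhrf1 passed (adjusted p = 0.0486), and Pola1, Mki67, Hmmr, Odc1, Fbl and Rps14 did not (adjusted p from 0.081 to 0.359). Of these 7 genes Odc1 passed without EM-plasma 1 (adjusted p = 0.0454) and none without EM-plasma 2 (from 0.133 to 0.695), and Odc1, Rps14 and Fbl did not pass without control 1 (0.0514, 0.0654 and 0.0765). Of 11 tested replication-dependent histone genes 0 passed, with 0 at an unadjusted p below 0.05 and 0 called by DESeq2, also 0 adjusted over the list alone. The libraries held poly(A) RNA, where 11 of the 25 list members could be tested and 2 had CPM above 1 in 2 samples. A change in histone transcripts could therefore be missed. The histone median was -0.073 while the mean was 0.09 and camera's direction was higher (adjusted p = 0.586), and the most abundant, Hist1h1c, was at 16.2 ± 0.11 and 18.1 ± 0.126 CPM.

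Of 30 tested p53 targets 3 fell and 1 rose (3 and 2 adjusted over the list alone; camera adjusted p = 0.909). Trp53inp1, a p53-induced nuclear protein gene, was 1.26-fold lower (adjusted p = 0.000135), Perp, an apoptosis effector, 1.16-fold lower (adjusted p = 0.0188), Sesn1 fell and Plk3 rose. Members called lower numbered 1, 0, 0 and 1 without control 1, control 2, EM-plasma 1 and EM-plasma 2, and 0 were called higher in each of these fits or by DESeq2. Of 22 apoptosis regulators 2 rose and 0 fell, the same adjusted over the list alone, and both inhibit apoptosis: Bcl2l1 (1.21-fold, adjusted p = 0.00557) and Bcl2 (1.19-fold, adjusted p = 0.0161). The list's median was -0.057, and camera gave it an adjusted p of 0.30 and fry 0.0231, both with the direction lower. Without control 2, Trp53inp1, Perp, Bcl2l1 and Bcl2 did not pass (adjusted p = 0.105, 0.196, 0.159 and 0.109). Nor did they without EM-plasma 1 (0.061, 0.193, 0.105 and 0.269), and without EM-plasma 2 or control 1 Perp (0.509 and 0.0632) and Bcl2 (0.276 and 0.075) did not, nor Bcl2l1 without EM-plasma 2 (0.181).

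Pigment genes changed in 5 of 25 tested members, 3 higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.578). Bcan, a proteoglycan gene, rose 1.58-fold, from 16.1 ± 0.228 to 25.5 ± 0.0175 CPM (adjusted p = 1.34e-06), Tfap2a, a neural crest transcription factor, 1.13-fold (adjusted p = 0.0278), and Slc24a4 rose as well. Rab27a, which carries melanosomes to the cell edge, and Apoe fell. Members called higher numbered 1, 1, 1 and 1 without control 1, control 2, EM-plasma 1 and EM-plasma 2, and members called lower 1, 0, 0 and 0. Mitf, the melanocyte lineage regulator, was at 442 ± 8.79 and 415 ± 3.88 CPM (adjusted p = 0.215) and Tyr, tyrosinase, at 42.7 ± 3.19 and 36.7 ± 2.06 CPM (adjusted p = 0.0532). Neither passed. Of 43 lysosome and autophagy genes 2 rose and 0 fell, the same adjusted over the list alone (1 called by DESeq2; camera adjusted p = 0.807). They were Sqstm1, the autophagy receptor p62 (1.17-fold, adjusted p = 0.000161), and Tfeb, the lysosomal transcription factor (1.22-fold, adjusted p = 0.0233). The calls of Tfap2a and Tfeb ended without control 2 (adjusted p = 0.142 and 0.255), EM-plasma 1 (0.522 and 0.205) or EM-plasma 2 (0.421 and 0.227), that of Tfap2a also without control 1 (0.0513), and that of Sqstm1 without EM-plasma 2 (0.0682).

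Most markers of other cell types lay below the count filter. Of 23 leukocyte markers 5 were tested and 0 passed, with 1 at an unadjusted p below 0.05 and 0 called by DESeq2, also 0 adjusted over the list alone. The most abundant, Cd68, was at 1.13 ± 0.379 CPM in controls and 1.62 ± 0.169 CPM in treated cells. That list's median was 0.34 while its mean was -0.21 and camera's direction was lower (adjusted p = 0.833). Of 9 tested fibroblast markers 1 rose and 0 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.336), namely Fn1, fibronectin, from 275 ± 11.2 to 324 ± 7.93 CPM (adjusted p = 0.00111). Erythroid, platelet and liver plasma protein markers had 3 tested members, too few for a list test, and 0 passed, with 0 at an unadjusted p below 0.05 and 0 called by DESeq2. Apoa2, a liver apolipoprotein gene, was at 0.842 ± 0.271 and 0.923 ± 0.305 CPM. Keratinocyte and endothelial markers also had 3 tested members, of which Vwf rose (from 3.8 ± 0.25 to 5.52 ± 0.158 CPM, adjusted p = 0.0281), 1 also adjusted over the list alone and 0 by DESeq2. The calls of Fn1 and Vwf ended without control 2 (adjusted p = 0.105 and 0.228), EM-plasma 1 (0.193 and 0.103) or EM-plasma 2 (0.0529 and 0.198), and that of Vwf also without control 1 (0.0753).

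**Figure D3:**
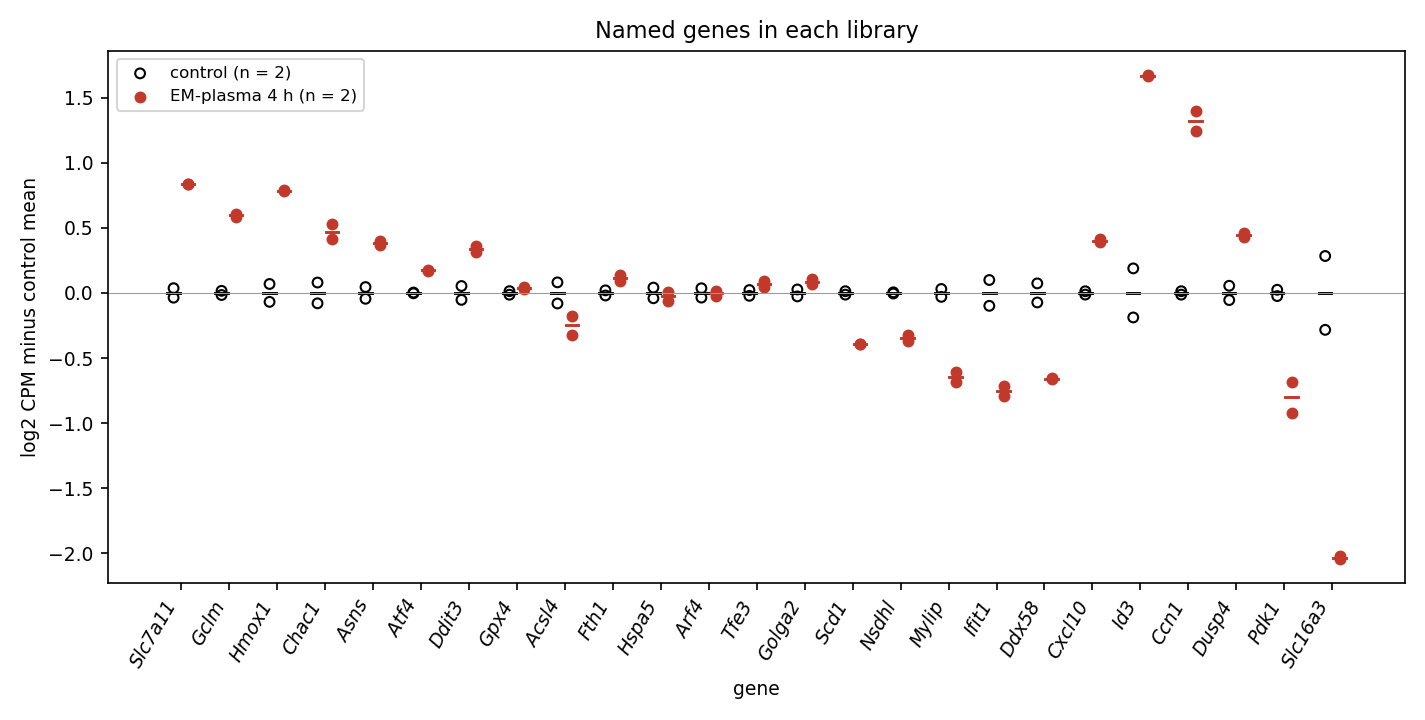
Log2 CPM of each library minus the mean of the control libraries (vertical axis) for 25 of the genes named in the text (horizontal axis), with open circles for the 2 control libraries, red points for the 2 EM-plasma libraries and short lines at each group's mean. Slc7a11, Hmox1 and Id3 lie above both controls in both treated libraries, Slc16a3 lies below, and Arf4 and Gpx4 stay close to the controls.

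Of the 70 named genes 53 were called, and 17 of these passed in each of the 4 fits that left out a library. Without control 2 the number was 19, without control 1 it was 40, without EM-plasma 1 it was 31 and without EM-plasma 2 it was 29. The control pair differed more than the treated pair. Over 12553 genes the mean chi-square per gene was 8.56 between the controls and 3.10 between the treated libraries, against 10.03 to 17.1 between groups. The median absolute log2 ratio was 0.094 between the controls, 0.057 between the treated libraries, 0.083 and 0.086 between control 1 and the treated libraries and 0.119 and 0.11 between control 2 and these. Control 2 stood apart in GC content: the Spearman correlation across genes of a library's deviation with GC was -0.43 in control 2 and 0.22, 0.25 and 0.09 in control 1, EM-plasma 1 and EM-plasma 2. Genes are not independent replicates. The first principal component held 49.4% of the variance and separated the groups. Exons of Arf4, Bcl2, Cog5, Creb3, Cxcl10, Ddit3, Fn1, Gclm, Golga2, Lims2, Scd2, Sqstm1, Tfap2a, mt-Co1 and mt-Nd5 overlap those of another gene. Because the strand setting of the counting is not given, their values are less certain.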

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

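The GC and length corrections and edgeR's newer dispersion were chosen after seeing the data. Other scalings (851 to 885 genes), voom (797), the newer dispersion (872) and the length correction (984) stayed within 1.5 times the 849 genes, with 53.3% to 60.6% of the calls higher. The alternative with edgeR's legacy dispersion is the reported fit itself, since this version takes it by default, and camera does not use the dispersion.

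With no filter beyond 1 count, 14 genes passed (13 higher, 1 lower, 3 at least 2-fold) of 22906 tested, and the fit's total degrees of freedom were 5.36 against 27.5. With CPM above 1 in 2 samples 41 genes changed at least 2-fold, since fewer low genes were tested. DESeq2 called 557 genes (277 higher, 29 at least 2-fold), and the cause was not tested. The exact test called 146 genes at least 2-fold, and the cause was not tested. At an adjusted p below 0.01 there were 371 genes (209 higher, 162 lower, 36 at least 2-fold). Against a fold of 1.2 there were 92 (66 higher, 26 lower, 31 at least 2-fold). Removing a GC trend per library gave 1622 genes (796 higher, 826 lower) at a coefficient of variation of 2.58% against 4.0%.

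Leaving out 1 library gave 71 to 547 genes, 48 to 258 higher, 23 to 289 lower and 7 to 48 at least 2-fold. Each was lowest without control 2, where total degrees of freedom were 5.27 against 27.5 with all libraries. The low counts therefore do not measure the weight of control 2 alone. Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated at 0.04 across genes. The second principal component held 26.8% of the variance. It was 17.5 and 6.81 in replicate 1 of control and EM-plasma, and -14.5 and -9.73 in replicate 2. The replicate block gave 1683 genes (832 higher, 851 lower), with all 849 calls kept. Its coefficient of variation was 3.14% against 4.0%, and its total degrees of freedom were 13664 against 27.5. That fit pooled the variance over all genes, so its higher counts do not show that the replicate numbers pair the samples.

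Of 12 called gene lists 0 were called with an estimated correlation, where 5 had an unadjusted p below 0.05. With few residual degrees of freedom this does not show that correlation between members undoes the calls. Fry kept 7 of the 12 and lost the immediate early, hypoxia, mitosis, MYC and ribosomal protein lists (adjusted p = 0.0851, 0.255, 0.11, 0.071 and 0.228), and it called 2 that camera did not, iron handling and apoptosis regulators. Other settings called 10 to 12 lists. Members called (higher and lower) went, after GC correction and with the replicate block, from 2 and 0 to 4 and 1 under both for iron handling, from 2 and 0 to 4 and 3 and to 3 and 2 for lysosome genes, from 2 and 0 to 2 and 2 under both for apoptosis, from 6 and 4 to 8 and 8 and to 7 and 7 for short-lived regulators, and from 1 and 3 to 2 and 5 and to 2 and 4 for p53 targets. Of 1189 values of named genes under alternatives, 1006 kept their side of the threshold, 175 lost it and 8 gained it. Of these values 19 changed sign, all in genes not past the test in either fit (Arf4, Atp5b, Hspa5, Gpx4, Canx, Mt1 and Apoa2). Of 53 called named genes 6 passed in every alternative: Id3, Lims2, Ccn1, Slc7a11, Gclm and Hmox1. With 2 libraries per group, simulated changes of 1.2-fold were found in 48.1% of cases, so small changes are often missed.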

Other observations

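The BMP, ERK, YAP and nuclear long noncoding groups, the tests of aryl hydrocarbon receptor and snoRNA host genes, and the comparison of biotypes were chosen after the values were seen. Targets of BMP signalling through SMAD1 and SMAD5 rose in 8 of 13 tested members and fell in 0, with a median log2 fold change of 0.59 (camera adjusted p = 1.41e-07; adjusted p = 0.101 with an estimated correlation). Beside Id1 and Id3 they included Smad9, from 17.5 ± 0.339 to 32.5 ± 0.404 CPM (mean ± SD, n = 2), the feedback inhibitor Smad6, from 10.9 ± 0.674 to 20.9 ± 0.402 CPM, and Atoh8, from 16.1 ± 2.28 to 33.6 ± 0.737 CPM. Genes that feed back on ERK signalling or act as its ETS effectors rose in 8 of 18 tested members and fell in 0, with a median of 0.24 (camera adjusted p = 4.41e-05; adjusted p = 0.101 with an estimated correlation). Spry4 went from 3.60 ± 0.138 to 6.68 ± 0.266 CPM, Etv5 from 19.95 ± 0.00626 to 28.2 ± 0.849 CPM, and Dusp6 from 106.8 ± 0.863 to 137.7 ± 2.94 CPM. Targets of YAP and TEAD rose in 5 of 16 tested members and fell in 0, led by Ccn1 and Ccn2, with a median of 0.18 (camera adjusted p = 4.41e-05; adjusted p = 0.101 with an estimated correlation). Ccn1 and Ccn2, and Dusp4, Dusp6 and Egr1 of the ERK group, were also called members of the immediate early list. Members called higher without control 1, control 2, EM-plasma 1 and EM-plasma 2 numbered 7, 6, 7 and 6 in the BMP group, 7, 2, 6 and 6 in the ERK group (1 was called lower without control 1) and 5, 1, 3 and 3 in the YAP group.

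Nuclear long noncoding RNAs rose in 6 of 10 tested members and fell in 0, with a median of 0.40 (camera adjusted p = 1.41e-07; adjusted p = 0.101 with an estimated correlation). Malat1 went from 167.1 ± 7.14 to 309.7 ± 14.7 CPM and Neat1, the scaffold of paraspeckles, from 28.2 ± 1.54 to 51.2 ± 0.239 CPM. Gas5, also among the members called higher, is a called member of the snoRNA host list below as well. Long noncoding members called higher numbered 4, 2, 4 and 4 without control 1, control 2, EM-plasma 1 and EM-plasma 2. Of the mitochondrially encoded genes mt-Nd1 and mt-Nd2 fell by 0.26 and 0.27 on the log2 scale, while mt-Rnr2, mt-Co1, mt-Nd4, mt-Nd5, mt-Cytb and mt-Nd6 rose by 0.23, 0.43, 0.35, 0.34, 0.32 and 0.83. The call of mt-Rnr2 ended without control 1, control 2 or EM-plasma 2 (adjusted p = 0.276, 0.334 and 0.827), that of mt-Nd2 without control 2 or EM-plasma 1 (0.0554 and 0.0614) and that of mt-Nd6 without control 2 (0.0853). Of 587 tested processed pseudogenes, whose median of 0.54 CPM lay far below the 31.1 CPM of all tested genes, edgeR's quasi-likelihood test called 0 (22 at an unadjusted p below 0.05), DESeq2 and voom 0 and the exact test 1, with 14 called lower without EM-plasma 1.

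Of 3 hypotheses tested on lists, each was called at the preset correlation (camera adjusted p = 1.12e-05, 0.00462 and 4.41e-05 in the order below). They were not called with an estimated one (camera adjusted p = 0.101 for each), where few residual degrees of freedom limit the test. This leaves them open. The rise of Id1 and Id3 may reflect a BMP target programme, and without those genes the list had 6 of 11 tested members higher and a median of 0.44. The rise of Cyp1a1 may reflect the aryl hydrocarbon receptor, and without Cyp1a1 the list had 1 of 6 tested members higher, with a median of 0.23. That member was Slc7a5. Cyp1b1, Ahrr, Tiparp, Nqo1 and Gsta1 did not pass (edgeR's quasi-likelihood test, adjusted p from 0.068 to 0.906). The rise of ATF4 targets may go with slower decay of snoRNA host transcripts when translation is repressed, and that list had 4 of 13 tested members higher, 1, 0, 1 and 0 without control 1, control 2, EM-plasma 1 and EM-plasma 2, and a median of 0.20.

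The 849 called genes differed in GC content, with a median of 52.8% in genes called higher, 46.6% in genes called lower and 49.4% in the rest. After a GC trend was removed from each library, 98.8% of the called genes were still called in the same direction. After a length trend was removed 98.6% were, which argues against that trend as the whole cause. For GC the share says less, since its removal lowered the coefficient of variation from 4.0% to 2.58% and smaller changes could pass. Median log2 fold changes of the ATF4, NRF2, cholesterol and interferon lists were 0.23, 0.15, -0.19 and -0.35 before its removal. They were 0.20, 0.15, -0.20 and -0.36 after it, which argues against GC as the whole cause in these lists. The fewest genes passed without control 2, in a fit that also had fewer degrees of freedom. How far the number of calls rests on control 2 stays open. A difference between cultures or library preparations of the groups stays open, as the labels name no batch. An effect of EM-plasma is a hypothesis that the same data cannot separate from these.

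Unclassified single-exon transcripts, the biotype TEC, 1 of the 12 biotypes compared after the values were seen, were more often higher than other genes: of 256 tested 26 were higher and 1 lower (Fisher's exact test, adjusted p = 2.71e-06), with 3 higher without control 1, 0 without control 2 (64 at an unadjusted p below 0.05), 12 without EM-plasma 1 and 13 without EM-plasma 2, and 7 by DESeq2, 25 by voom and 49 by the exact test. Genomic DNA in the treated libraries is argued against, since reads of 1730 olfactory and vomeronasal receptor genes had a treated to control ratio of 0.994 (95% exact interval 0.845 to 1.17), below the 1.25 (1.24 to 1.27) of all TEC genes, counting error only. A GC trend is also argued against, as the median log2 fold change of the tested TEC genes was 0.52 before and 0.56 after its removal. TEC genes inside a gene on the same strand rose more than the others, by 0.59 on the log2 scale (95% bootstrap interval 0.41 to 0.78; two-sided permutation p = 1e-05, the smallest that 100000 permutations can give), which goes with unspliced RNA of their host genes as a candidate source. Fisher's test, the bootstrap and the permutation treat genes as independent and cover the spread between genes, not between libraries. The 26 of 256 TEC genes called higher stand against 456 of all 13664 tested genes. Tested TEC genes had a median of 0.41 CPM, far below the 31.1 CPM of all tested genes, so their single calls rest on few reads. The host genes themselves had a median log2 fold change of -0.046. Whether transcription, splicing or the nuclear share of the RNA differed stays open.

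The 13 interferon list members called lower were all still called lower after the GC trend was removed, 13 of 13, though smaller changes could pass there. The median log2 fold change of the whole list was -0.35 before and -0.36 after, which argues against that trend. Loss of contaminating leukocytes is argued against by their markers. Ptprc, Adgre1, Itgam and Tyrobp were among the markers at 0 CPM in both groups. The most abundant, Cd68, had a mean of 1.13 CPM in the controls (upper bound 1.89 CPM), while B2m fell by 20.1 CPM. The scarce markers Fcer1g and Lyz2, however, were at 0.612 and 0.311 CPM in controls against 0.258 and 0.129 CPM in treated cells (edgeR's quasi-likelihood test, adjusted p = 0.124 and 0.266). The list's median log2 fold change was -0.33, -0.31, -0.31 and -0.33 without control 1, control 2, EM-plasma 1 and EM-plasma 2, against -0.35 with all libraries. These values argue against 1 library deciding the size of the list's fall. That 100% of the 13 members lay below 0 in each fit decides nothing, since their treated libraries lay below both controls. Which single members passed depended on the library left out, as given above. A biological fall in interferon signalling after EM-plasma is a hypothesis, found and tested on the same data. A difference between cultures in basal interferon signalling stays open.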
